A study of Papio anubis with 8 samples.

How the data were processed

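Total RNA from the hippocampus of fetal olive baboons (Papio anubis) at 0.9 of gestation was sequenced in 8 libraries. Per the labels' protocols, RNA was extracted with an RNeasy column kit and libraries were prepared from 25 ng of total RNA with a strand-specific NEBNext kit. The design text speaks of mothers that differed in adiposity and leptin level. The labels of the 8 samples differ in the title alone, and no title gives the maternal group. The title of AMB3 ends in L1000, and the other titles end in S and the number of the library. The labels do not say what these endings stand for. All 8 libraries were therefore treated as unassigned: no group of libraries was compared with another, and values are given per library or as median and range. The labels do not say that each library came from a different fetus.

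The deposited table holds 37053 genes with a raw and a normalized value for each library. The raw values are estimated counts per RefSeq gene, per the file headers, in which the annotation is named RefSeq and the columns raw. Between 22.5% and 26.7% of the values above 0 were whole numbers (tolerance 0.001), and the rest were fractional, as counters that divide reads among genes or transcripts give. The aligner, the counter and the genome build are not given in the sources used here. DESeq is named, without a version, per the submitters' processing notes. All 37053 gene identifiers and symbols matched the RefSeq gene table of the assembly Panubis1.0, with 99.98% of start and 99.96% of end positions equal, and the coordinates below are those of the deposited table on that assembly. Some genes of the lists described below had no row under their symbol and are not analysed here (528 of 564 listed genes had one).

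The deposited normalized values are on a log2 scale. In each of 15582 genes with more than 20 counts in every library, they equalled log2 of the raw value over a factor per library, minus the median of that quantity over AMB3, AMB8 and AMB10. Taken relative to AMB3, the deposited values differed from what the factors give by at most 1.7e-06. The median of the deposited values over AMB3, AMB8 and AMB10 was 0, within rounding, in 100.0% of these genes. No other trio of libraries gave a median of 0 in more than 47.1% of these genes. The factors lay between 0.724 (AMB9) and 1.30 (AMB10), close to the factors computed here by the trimmed mean of M-values (0.723 and 1.30). The labels do not say why these 3 libraries served as the baseline, and the rule was not used to group libraries. A log2 value of 0 in all libraries stood in 8623 genes.

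Estimated counts were rounded to whole numbers. Genes were kept by edgeR's filterByExpr with a minimum count of 10 and no groups. It asks for the minimum in all 8 libraries, scaled to library size, so that it is 10 counts at the median library size. This left 16874 genes, 14947 of them protein-coding. This filter leaves out genes that are near 0 in some libraries, among them LEPR and the Y-linked genes, whose values are given with their counts. Library sizes were scaled by the trimmed mean of M-values in edgeR, and levels are given as CPM (the count scaled to a library of 1000000) on those sizes or as log2 CPM with a prior count of 2. The range of a gene is the difference in log2 CPM between its highest and lowest library. The expected range from counting error was taken from counts simulated from a Poisson law with the same means and library sizes. The spread over all 8 libraries was summarised by the common dispersion of an intercept-only model in edgeR, and it includes any effect of the mother, of fetal sex and of dissection.

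Before the data were examined, 43 gene lists, 20 pairs of lists and the rule for the genes named were written down, along with all alternatives except those stated as added later. The score of a list in a library is the median over its tested members of log2 CPM minus the median of that gene over libraries. The range of each score was set against 10000 random lists of the same size, matched on mean expression in 20 bins. This percentile describes these libraries and is not a p-value. Lists with fewer than 4 tested members have none. Co-variation of a list is the median Spearman rho over pairs of its members, set against 1000 random lists. Each range was recomputed without each library in turn, and a library whose removal shrank it by more than 1.5 times is named. Pairs of list scores were related over the 8 libraries by Pearson's r and Spearman's rho with exact 2-sided permutation p-values over all 40320 pairings and Benjamini-Hochberg adjustment over the pairs. No pooled r is given where the largest gap in either score exceeded 0.5 of its range with at least 2 libraries on each side. Genes are named by 4 rules: up to 4 members of each list with the highest median CPM and the 1 of largest range; the 20 tested genes of largest range that carry a symbol and have a median count of at least 50; the 10 genes of highest median CPM; and a fixed set of leptin, adipokine, insulin, steroid receptor and neural genes. Some genes that these rules name are not reported here.

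The 28 pairs of libraries were checked for a library present more than once. The chi-square statistic over 16731 genes, divided by its degrees of freedom, lay between 41.7 and 300.3, so no pair was within sampling noise. The procedure was tested on simulated counts in which 200 genes were raised in 1 library. Among genes raised by 2-fold, 86.0% had a log2 range of at least 1 and 94.0% were highest in the right library, over 17844 genes. At 4-fold, 8-fold and 16-fold both shares were 100.0%. The dispersion of unchanged genes came out at 0.0397 where 0.04 had been simulated. The common dispersion over the real libraries was higher, at 0.0769. The shares above hold for the simulated spread only, and the share of unraised genes with such a range is not given. Of 20 lists of 10 genes shifted by 1 log2 unit in 1 library after shuffling each gene over libraries, 20 passed into the top 2.5% of random lists, and 0 of 20 did so without the shift. The shuffling also removed co-variation among the genes, which many of the real lists had. The 0 of 20 therefore gives no rate at which such lists would pass without a shift.

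Alternatives were DESeq2 size factors, total-count scaling, the deposited log2 values, no filter beyond 1 count, a minimum count of 50, prior counts of 0.5 and 5, leaving out mitochondrially encoded and globin genes before scaling, thinning all libraries to the smallest total, the mean instead of the median over list members, and leaving out each library. A filter on a mean count of 10, and lists of further hippocampal and of cortical marker genes, were added after seeing the data. Intervals of single counts are 95% Poisson intervals and those of shares 95% Wilson intervals. They, and the limit of 3 counts that a count of 0 allows, cover counting error only. Work was done in R 4.3.3 with edgeR 4.0.16 and DESeq2 1.42.0, and in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3.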

Results

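Transcript levels were measured in the hippocampus of fetal olive baboons at 0.9 of gestation, in a study of offspring of mothers that differed in adiposity and in the level of leptin, the hormone that fat tissue secretes. The labels give no maternal group for any of the 8 libraries, so the values below describe how the libraries differed and compare no groups. Total counts ran from 40404878 in AMB9 to 71648654 in AMB10, with a median of 58168732. Between 22973 and 24838 genes had at least 1 count, and between 17992 and 19427 had at least 10. The 10 most counted genes of a library took 2.70% to 3.68% of its counts. The 10 genes of highest median CPM included 8 mitochondrially encoded genes, among them COX1 with 7333 CPM, and LOC101018365 with 3131 CPM.

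Myelin genes differed most between libraries among the 39 lists with at least 4 tested members. The score of the myelinating oligodendrocyte list ran from -1.22 in AMB3 to 1.93 in AMB10, a range of 3.15 on the log2 scale or 8.90-fold, against a range of 0.011 from counting error. All 11 members had a log2 range of at least 2, and they varied together (median rho 0.976, above each of the 1000 random lists). MBP, myelin basic protein, stood at 1698 CPM in AMB10, 1580 in AMB4, 1096 in AMB8 and 776 in AMB6, and at 270 in AMB3 and 285 in AMB5. MOBP ranged from 51.8 to 596 CPM, CNP, a phosphodiesterase of the myelinating cell, from 96.9 to 413 CPM, and OPALIN, a membrane protein of oligodendrocytes, from 2.61 to 58.2 CPM. Genes of oligodendrocyte precursors spanned a smaller range of 1.40, from -0.72 in AMB7 to 0.68 in AMB10. PDGFRA, the growth factor receptor of precursors, lay between 42.4 and 89.4 CPM. BCAS1 lay between 58.9 and 236 CPM, and GPR17 between 33.1 and 122 CPM, both genes of the stage between precursor and myelinating cell. OLIG1, a lineage transcription factor, had the largest range of that list, from 1.93 to 14.2 CPM.

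**Figure D1:**
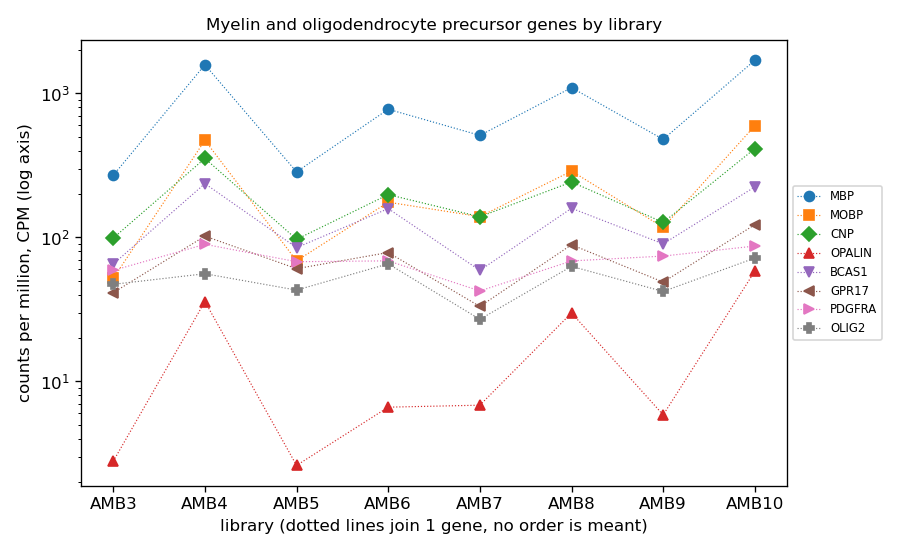
Levels in CPM on a log axis for 4 myelin genes and 4 genes of oligodendrocyte precursors in each of the 8 libraries; each symbol is 1 gene in 1 library. MBP reached 1698 CPM in AMB10 and 270 CPM in AMB3, while PDGFRA stayed between 42.4 and 89.4 CPM.

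Genes of the meninges and of fibroblasts came next, with a score range of 2.49 from -1.34 in AMB8 to 1.15 in AMB7, and 8 of 9 members had a range of at least 2. The collagen gene COL1A2 stood at 152 CPM in AMB7 and 135 in AMB4, and at 21.3 in AMB5 and 23.4 in AMB8. COL1A1 and COL3A1 were highest in AMB4, with 130 and 141 CPM. The proteoglycan DCN was at 137 CPM in AMB3 and 9.12 in AMB8, and PTGDS, a prostaglandin synthase of the leptomeninges, between 72.4 and 298 CPM. Pericyte and smooth muscle genes had a range of 0.66. RGS5, PDGFRB and NOTCH3 each had a log2 range of at most 1.08, whereas MYH11, the heavy chain of smooth muscle myosin, stood at 59.1 CPM in AMB4, 16.1 in AMB3 and no more than 5.55 elsewhere. Other contractile genes of smooth muscle in this list, chosen after their values were seen, had the same 2 highest libraries. ACTA2, smooth muscle actin, was at 128.5 CPM in AMB4, 47.6 in AMB3 and 5.19 to 17.2 elsewhere, and TAGLN at 80.7, 34.3 and 12.5 to 20.4 CPM. Genes of ependyma and cilia ranged over 1.45, which fell to 0.95 without AMB10, the highest library. There PIFO, a gene of primary cilia, was at 14.6 CPM, against 0.231 to 4.26 in the other libraries. FOXJ1, the master regulator of motile cilia, varied from 115 to 148 CPM. The endothelial list had a range of 0.43, above 96.6% of random lists, with PECAM1 between 34.7 and 50.2 CPM. Of 8 choroid plexus genes 2 passed the filter, AQP1 and KL. TTR, the transthyretin that choroid plexus secretes, was at most 2.47 CPM and had no count in AMB5, which allows up to 0.0659 CPM. Of red blood cell genes 3 were tested, and the fetal globin HBG2 ranged from 22.4 CPM in AMB8 to 114 in AMB9. Blood leukocytes had 3 tested genes, among them CD3E at 2.28 to 5.49 CPM.

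Astrocyte genes varied together (median rho 0.738) over a score range of 0.98, from -0.47 in AMB7 to 0.52 in AMB10. GFAP, the astrocyte intermediate filament, ran from 552 CPM in AMB7 to 1613 in AMB10, and the glutamate transporters SLC1A2 and SLC1A3 were likewise lowest in AMB7 (1151 and 541 CPM) and highest in AMB10 (2272 and 1002 CPM). Radial glia genes ranged over 0.84, with AMB7 lowest and AMB8 highest, and TNC, an extracellular matrix protein of radial glia, was at 128 and 318 CPM in these libraries. Microglia genes ranged over 0.94, from -0.57 in AMB8 to 0.37 in AMB6, and over 0.63 without AMB8. The fractalkine receptor CX3CR1 was at 13.6 CPM in AMB8 and 40.7 in AMB4, and P2RY12, the purinergic receptor of resting microglia, at 13.3 and 31.9 CPM in these libraries. Cell cycle genes were low throughout, with MKI67 at 2.64 to 7.40 CPM and PCNA at 24.0 to 29.9 CPM, and their range of 0.51 exceeded 91.7% of random lists.

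Neuronal lists had smaller ranges than these glial lists, but single members differed by far more. The excitatory neuron score ranged over 0.45, from -0.30 in AMB3 to 0.15 in AMB5. SLC17A7, the main vesicular glutamate transporter of cortical neurons, lay between 806 and 1365 CPM, and CAMK2A between 899 and 2360 CPM. The list of hippocampal field and dentate gyrus markers had a range of 0.61, and its members did not vary together (median rho -0.01). FIBCD1 was at 400 CPM in AMB8 and 367 in AMB10, at 84.1 in AMB3 and 76.9 in AMB4, and between 9.01 and 22.3 elsewhere. PROX1, the transcription factor of dentate granule cells, stood at 96.7 CPM in AMB8, 81.9 in AMB10 and 49.1 in AMB3, against 14.4 to 33.6 elsewhere. MEF2C, an activity-dependent transcription factor, was lowest in the same libraries, with 123 CPM in AMB8, 140 in AMB10 and 326 in AMB3, and 1201 to 1782 in the other libraries. Interneuron genes ranged over 0.82, which fell to 0.41 without AMB8. In AMB8 the GABA-synthesizing enzyme GAD1 was at 129 CPM and the neuropeptide SST at 59.1, where the highest libraries had 311 and 232 CPM. Immature neuron genes ranged over 0.51, and over 0.21 without AMB9. DCX, a microtubule protein of migrating neurons, was at 657 CPM in AMB9 and between 271 and 473 elsewhere, whereas NEUROD1 was highest in AMB8 (82.5 CPM) and AMB10 (63.7 CPM). The list of thalamic and other forebrain genes had a range of 0.48, above 86.9% of random lists, and 0.27 without AMB5. FOXP2 had the largest range of its members, from 1.59 CPM in AMB8 and 3.83 in AMB10 to 67.6 in AMB7.

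**Figure D2:**
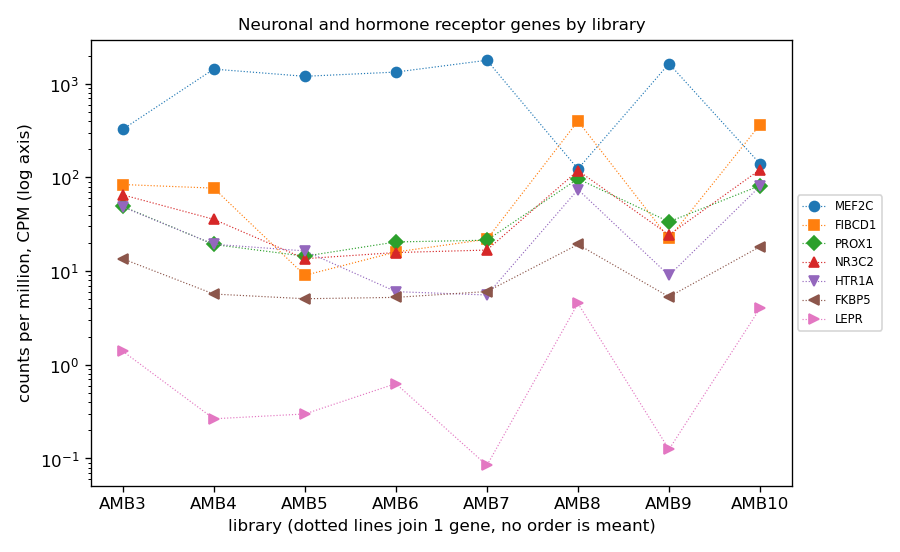
Levels in CPM on a log axis for 7 neuronal and hormone receptor genes in each of the 8 libraries; each symbol is 1 gene in 1 library. FIBCD1, PROX1, NR3C2, HTR1A, FKBP5 and LEPR had their highest values in AMB8 and AMB10, where MEF2C had its lowest.

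The leptin receptor LEPR (chromosome 1, 63973519 to 64038117) was at 4.52 CPM in AMB8 (95% Poisson interval 4.03 to 5.06, 305 counts), 4.01 in AMB10 (3.56 to 4.51, 285 counts) and 1.40 in AMB3 (1.06 to 1.81, 57 counts). The other libraries had between 0.0843 and 0.630 CPM, from 5 to 34 counts, so LEPR did not pass the filter. LEP, the leptin gene, had 2 counts in AMB6 and none in any other library, which allows up to 0.0743 CPM in the shallowest. Downstream of the receptor, levels were closer: STAT3, the transcription factor of leptin signalling, lay between 57.9 and 67.8 CPM, and its feedback inhibitor SOCS3 between 0.782 and 1.96 CPM, a log2 range of 1.29 that fell to 0.79 without AMB5. The leptin and STAT3 list had a range of 0.25, above 54.6% of random lists. This score covers its 11 tested members, without LEPR and LEP. The adipokine and energy sensing list had a range of 0.20, above 58.4%. That small score range does not mean even members: 10 of its 14 members had a log2 range of at least 1, and 5 of at least 2. CDH13, for example, ranged from 56.2 CPM in AMB8 to 340 in AMB5. The adiponectin receptors ADIPOR1 (95.6 to 127 CPM) and ADIPOR2 (72.4 to 82.9 CPM) had log2 ranges of 0.41 and 0.20, which fell to 0.27 without AMB5 or AMB10 and to 0.09 without AMB3. The neuropeptide Y receptor NPY2R was at 13.1 CPM in AMB10, 10.1 in AMB8 and 5.18 in AMB3, against 0.794 to 1.39 elsewhere. CRHR1, a receptor of corticotropin-releasing hormone, was lowest in AMB10 and AMB8 (7.24 and 9.53 CPM). Insulin and IGF genes ranged over 0.36, above 99.6% of random lists, from -0.18 in AMB8 to 0.17 in AMB4. The insulin receptor INSR ranged from 9.59 to 17.5 CPM and IGF1R from 52.1 to 81.0 CPM, both lowest in AMB8, and the log2 range of INSR fell from 0.86 to 0.48 without AMB8. IRS4, an insulin receptor substrate, ranged from 0.239 CPM in AMB8 to 13.9 in AMB3, a log2 range of 5.66 that fell to 3.66 without AMB3.

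The glucocorticoid list as a whole had a range of 0.26, above 80.1% of random lists, yet 4 of its 13 members had a log2 range of at least 2. NR3C2, the mineralocorticoid receptor (chromosome 3, 40888680 to 41252367), stood at 121 CPM in AMB10, 118 in AMB8 and 65.2 in AMB3, and between 13.6 and 35.7 elsewhere. The glucocorticoid receptor NR3C1 ranged from 26.5 to 42.6 CPM. FKBP5, a chaperone that glucocorticoids induce, was at 19.3 CPM in AMB8, 18.3 in AMB10 and 13.5 in AMB3, and between 5.07 and 6.05 elsewhere. HSD11B1, which regenerates active glucocorticoid, ranged from 0.435 CPM in AMB7 to 7.51 in AMB8 and 7.45 in AMB10. Members did not all rise in these libraries, and the glucocorticoid score was lowest in AMB8 (-0.19) and highest in AMB7 (0.07). PER1, another member, was at 49.5 CPM in AMB8, 45.3 in AMB10 and 93.9 in AMB7. Immediate early genes ranged over 0.80 and varied together (median rho 0.571). The score was lowest in AMB3 (-0.48) and AMB10 (-0.36) and highest in AMB6 (0.32), and EGR1 lay between 53.5 and 140 CPM.

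The scores of the 3 synaptic lists differed in how far they ranged. The glutamate receptor and postsynaptic density list had a range of 0.10, above 3.43% of random lists, with the obligatory NMDA receptor subunit GRIN1 between 518 and 641 CPM and the scaffold DLG4 between 498 and 663. Its member of largest range was GRIA4, from 30.5 CPM in AMB8 to 132 in AMB7. GRIA1 went the opposite way, with 1105 CPM in AMB8 and 438.5 in AMB7. Members of this list had a median log2 range of 0.615, against 0.601 for synaptic vesicle genes. The small score range therefore does not mean even members. Scored by the mean over members, the list had a range of 0.273. Synaptic vesicle genes had a score of 0.30 in AMB5 and between -0.10 and 0.03 elsewhere, so that the range of 0.39, above 99.4% of random lists, fell to 0.13 without AMB5. The vesicle protein SYP was at 1332 CPM in AMB5. GABA receptor genes ranged over 0.33, above 95.7% of random lists, and over 0.17 without AMB8, where GABRA4 was at 8.58 CPM against 68.3 in AMB4. Axon guidance genes ranged over 0.34, and NRP1, a semaphorin receptor, stood at 100.4 CPM in AMB8, 93.1 in AMB10 and 63.2 in AMB3, against 8.89 to 20.6 elsewhere. Receptors for serotonin, dopamine and acetylcholine ranged over 0.73. HTR1A, an inhibitory serotonin receptor, was at 80.6 CPM in AMB10, 74.3 in AMB8 and 48.5 in AMB3, and between 5.56 and 19.4 elsewhere. The neurotrophin list ranged over 0.50, and over 0.27 without AMB7, in which BDNF was at 14.6 CPM, against 30.4 to 58.0 elsewhere. Its receptor NTRK2 lay between 535 CPM in AMB8 and 904 in AMB4, and its log2 range of 0.76 fell to 0.45 without AMB8.

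Mitochondrially encoded genes ranged over 0.63, and over 0.27 without AMB7. They took 2.249% of the counts in AMB7 (95% Wilson interval 2.245% to 2.252%) and 3.37% in AMB3 (3.364% to 3.375%). Nuclear genes of oxidative phosphorylation ranged over 0.35, with ATP5F1B between 717 CPM in AMB7 and 923 in AMB5. Glycolysis genes ranged over 0.38 (above 96.7% of random lists), and GAPDH lay between 488 and 699 CPM. Ribosomal protein genes ranged over 0.48, from -0.30 in AMB10 to 0.17 in AMB9, and over 0.27 without AMB10. Levels of GAPDH and of ribosomal protein genes are uncertain to the extent that the counting split reads among similar copies, which was not examined by sequence. Hypoxia genes had a range of 0.21 (above 42.6%), with VEGFA between 58.2 and 98.1 CPM. Heat shock and unfolded protein response genes had a range of 0.31 (above 86.9%), and 0.20 without AMB7. Oxidative stress genes had one of 0.33 (above 96.6%), with HMOX1, the inducible heme oxygenase, between 1.87 and 7.38 CPM.

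Genes of DNA methylation ranged over 0.31, above 88.5% of random lists, and over 0.17 without AMB3. The methyltransferases DNMT1 (74.4 to 90.7 CPM) and DNMT3A (70.0 to 92.6 CPM) varied little, while the demethylase TET3 ranged from 88.2 CPM in AMB3 to 241 in AMB7. Histone modifiers ranged over 0.24 (above 93.2%), and HDAC9 had the largest range among them, from 23.1 CPM in AMB8 to 75.0 in AMB4. Interferon response genes ranged over 0.75, with AMB10 highest and AMB7 lowest. The interferon-induced IFI6 was at 146 CPM in AMB8 and 31.5 in AMB7. Inflammatory genes had a range of 0.30, above 55.4% of random lists, but PTGS2, the inducible cyclooxygenase, was at 0.269 CPM in AMB8, 0.280 in AMB10 and 0.690 in AMB3, against 5.41 to 10.9 elsewhere. Sterol and fatty acid synthesis genes ranged over 0.50. Lipid transport genes ranged over 0.38, and over 0.19 without AMB7. FABP5, a fatty acid carrier, was at 1.24 CPM in AMB4 and between 13.7 and 24.9 elsewhere. In all, 24 of the 39 lists had a range in the top 2.5% of random lists. Lists drawn like the random ones would place 1.0 there. This is no chance expectation for these lists, since members that vary together keep a wider range of their median than unrelated genes. With the deposited log2 values the number was 14. There the random lists were matched on the mean baseline-centred value and not on expression. The numbers therefore cannot be compared.

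**Figure D3:**
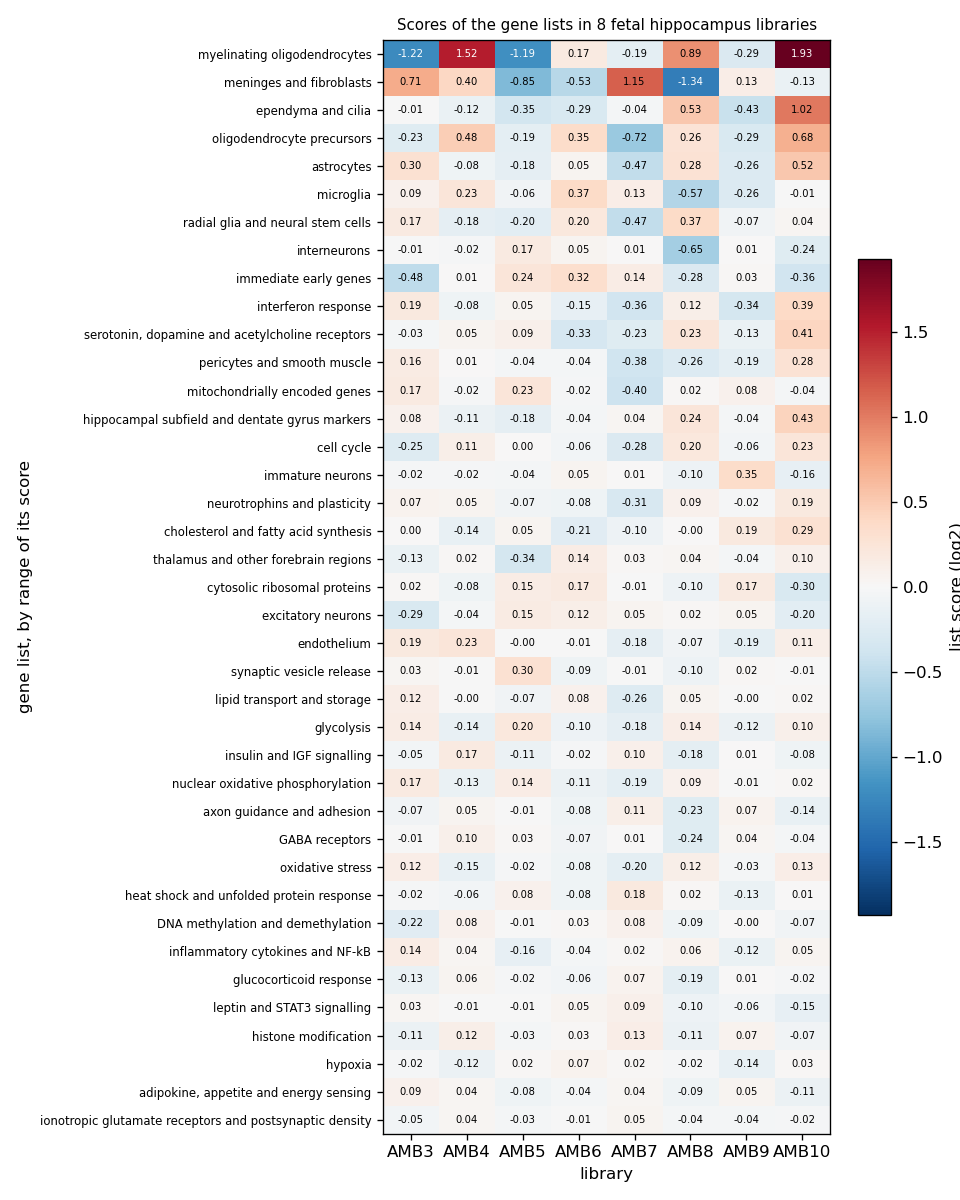
Scores of the 39 gene lists with at least 4 tested members (rows, by range) in the 8 libraries (columns); colour and number give the median log2 difference of the members from their own median over libraries. The myelin list runs from -1.22 in AMB3 to 1.93 in AMB10, and the glutamate receptor list stays between -0.05 and 0.05.

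Of the 20 named genes of largest range, several had their extremes in AMB8 and AMB10. NEUROG2, a proneural transcription factor (chromosome 3, 76629729 to 76632486), stood at 26.1 and 20.7 CPM in these libraries and between 0.196 and 5.25 elsewhere. AOX1, an aldehyde oxidase (chromosome 10, 84191071 to 84279066), was at 154 and 118 CPM and between 1.84 and 37.6 elsewhere, and TSPAN18 at 276 and 189 CPM, with 101.2 in AMB3 and 5.38 to 12.7 elsewhere. Conversely, ABI3BP, an extracellular matrix binding protein (chromosome 2, 20666587 to 20915184), was at 1.03 CPM in AMB8 and 5.31 in AMB10, against 23.4 to 95.3 elsewhere. The retinoic acid receptor RARB was at 1.94 and 4.29 CPM, with 4.91 in AMB3 and 20.03 to 80.5 elsewhere. The transcription factor OVOL2 was at 0.733 and 0.727 CPM against 7.15 to 36.5, SPON2 at 0.748 and 0.769 against 1.91 to 37.4, and FAT2 at 0.269 and 0.545 against 2.85 to 12.97. Other genes had their highest level in another library. VGLL3 was at 37.1 CPM in AMB3 and no more than 7.07 in another library, and TSHZ2 ranged from 3.25 CPM in AMB8 and 9.05 in AMB10 to 128 in AMB3. FFAR4, a receptor for long-chain fatty acids, was at 22.8 CPM in AMB5 and at most 5.35 elsewhere. The bacterial sensor NOD2 was at 24.6 CPM in AMB7 and 18.6 in AMB9, and lowest in AMB10 (0.378 CPM) and AMB8 (0.643 CPM). The matrix proteoglycan OGN was at 39.5 CPM in AMB7.

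Across all 16874 tested genes, 6084 (36.1%) had a log2 range of at least 1 and 1518 (9.0%) of at least 2. Counting error alone gave 358 and 0 of 18124 simulated genes, and the median range was 0.77 against 0.14. The common dispersion corresponded to a biological coefficient of variation of 27.7%, with 26.8% to 28.6% when 1 library was left out. The numbers of genes depend on the filter: with a minimum count of 50, 4030 and 750 genes had these ranges.

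None of the 19 relations between list scores that could be pooled passed Benjamini-Hochberg adjustment by exact permutation, with 0 by Pearson's r and 0 by Spearman's rho, and 3 had an unadjusted Pearson p under 0.05. The smallest p that the permutations allow is 5e-05. For nuclear against mitochondrially encoded respiratory genes r was 0.814 (exact permutation p = 0.0042, adjusted 0.08) and rho 0.762 (p = 0.037, adjusted 0.23), with r = 0.695 without AMB3 and AMB7. For astrocyte against lipid transport genes r was 0.748 (exact permutation p = 0.024, adjusted 0.18) and rho 0.81 (p = 0.022, adjusted 0.23), with r = 0.795 without AMB7 and AMB10. For myelin against precursor genes r was 0.773 (exact permutation p = 0.029, adjusted 0.18) and rho 0.762 (p = 0.037, adjusted 0.23), falling to r = 0.477 without AMB4 and AMB10. Excitatory neuron and astrocyte scores had r = -0.667 (exact permutation p = 0.074, adjusted 0.35) and rho = -0.667 (p = 0.083, adjusted 0.32), and r = -0.114 without AMB3 and AMB10. Leptin and insulin signalling scores had r = 0.514 (exact permutation p = 0.19, adjusted 0.61) and rho = 0.571 (p = 0.15, adjusted 0.48), and r = 0.371 without AMB7 and AMB10. For leptin signalling against glucocorticoid genes r was 0.277 (exact permutation p = 0.51, adjusted 0.88) and rho 0.262 (p = 0.54, adjusted 0.78), and r 0.211 without AMB7 and AMB10. Hypoxia and glycolysis scores fell into separate clusters, and that relation was not tested. The labels give neither a maternal group nor a sequencing batch within which to repeat these relations.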

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

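All tests of explanations in this part were chosen after the patterns had been seen. Of 83 measures examined over the 8 unassigned libraries, 7 had a highest or lowest library far from the others, with a gap to the nearest library that took an unusually large share of the whole range. For independent measures not chosen by their values, chance alone gives about 1 in 20, or 4.2 of 83. Some of the genes here, AQP1 and SPATA22 among them, were chosen for their large range, and all measures share the same libraries. The 7 therefore cannot be read against 4.2. Among list scores, AMB5 was the highest library for synaptic vesicle genes (gap of 0.673 of the range), AMB9 for immature neuron genes (0.593), and AMB7 the lowest for mitochondrially encoded genes (0.566). Among single genes the share was 0.569 for the water channel AQP1, lowest in AMB3 with 0.493 CPM, and 0.549 for ADIPOR2, also lowest in AMB3, with 72.4 CPM. It was 0.532 for SPATA22, a meiosis gene at 0.314 CPM in AMB8, and 0.532 for BDNF, at 14.6 CPM in AMB7. No measure of library depth or composition stood out in this way.

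The myelin score, with its 8.90-fold range, was weighed against its technical and compositional explanations. Under 5 alternatives of scaling and depth the range was at least 3.154, against 3.15 as reported. This argues against depth, and against the choice among these scalings, as its source. The scalings differed little, with trimmed mean factors relative to total counts from 0.954 in AMB5 to 1.024 in AMB6. They could hardly have moved the range, so the test says little about scaling in general. The score had r = 0.429 with the first principal component of the libraries (exact permutation p = 0.29, adjusted 0.37 over 10 relations), rho = 0.381 (p = 0.36, adjusted 0.51), and r = -0.419 without AMB8 and AMB10, so 8 libraries do not decide whether myelin follows that axis. The libraries with under 100 counts over 5 Y-linked genes covered 100% of the range of the score, from AMB3 to AMB10, which argues against fetal sex as its sole source and leaves a part open. The share of white matter in the tissue taken, the stage of oligodendrocyte maturation and the maternal groups, which the labels do not give, remain open and were not tested.

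Several genes annotated as members of families of copies were near absent in some libraries and abundant in others. For 48 of them, with a log2 range of at least 3, a candidate explanation is that reads moved between near-identical copies, which would leave the total over a family more even than the copy. The family total had less than 0.5 of the range of the copy for 24 of them, against 25 to 31 (median 28) with random partner genes, but this count decides nothing. Families were formed from descriptions with words such as "like" and "pseudogene" removed, so that some hold distinct genes (ITGBL1, CERKL), 3 had no other counted member, and in 16 of the 24 the copy held under 20% of the total in every library. Read sharing therefore stays open, also for LOC101001348, a copy of ribosomal protein L32 on chromosome 13, which ranged from 0.407 CPM in AMB4 to 55.6 in AMB3 while its family lay between 100.3 and 166.5 CPM, and a variant of single animals against the reference was not tested.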

How the results depend on the processing

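The mean count filter was chosen after seeing the data. The numbers of genes with a log2 range of at least 1 and at least 2 moved with the filter, since it sets which genes are counted: 15836 and 5890 with no low-count filter, 4030 and 750 with a minimum count of 50, and for a range of at least 2, 3046 with the mean count filter. Under the other settings they stayed within 1.5 times of 6084 and 1518. Leaving out 1 library gave 5410 to 5945 and 1253 to 1460 genes. The number of lists in the top 2.5% of random lists was 24, and it ran from 18 to 28 without 1 library. Scored by the mean over members, the number was 19. Under the remaining processing alternatives except the deposited values, it was 23 to 26. It was 14 with the deposited normalized values, but these are centred on a baseline in each gene. The random lists were then matched on the centred values and not on expression, so 14 cannot be set against 24. No relation between list scores passed adjustment under any setting, with 0 throughout. For 11 of the alternative values of the 6 relations given, the scores fell into separate clusters or had no members left, and no r is given. This exclusion was applied to the alternatives after their values had been seen, and 1 of them, leptin signalling against glucocorticoid genes scored by the mean over members, had the opposite sign to its main value. The remaining 61 values under other processing and 42 without 1 library kept their direction. The relation of leptin to insulin signalling ran from r = 0.083 without AMB7 to r = 0.872 without AMB4. Of 461 list ranges under other processing 26 moved by more than the spread of the score over libraries, and of 336 without 1 library 29 did. Ranges of named genes moved in 0 of 323 and 14 of 272 cases. Genes near the filter limit, such as LEPR in AMB9 with 5 counts (0.0406 to 0.292 CPM), are limited by counting error.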

Other observations

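The tests of explanations in this part were chosen after the result had been seen, and the second list of hippocampal genes and the cortical list were written after the genes that lead the first component had been seen. Along the first principal component of the 1000 most variable genes, which held 49.6% of their variance, AMB8 lay at 39.4, AMB10 at 36.0 and AMB3 at 13.04. The others lay at -13.4 (AMB4), -15.1 (AMB5), -17.1 (AMB6), -17.5 (AMB9) and -25.4 (AMB7). The 3 libraries with the highest coordinates are those on which the deposited values were centred. The labels do not say what they are, and they were not tested as a group against the rest. LEPR, NR3C2, FKBP5, NPY2R, HTR1A, PROX1 and FIBCD1 took high values at the upper end, and MEF2C, FOXP2, RARB and PTGS2 low ones.

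Sequencing depth was tested as a source of this axis. With all libraries thinned to the smallest total, the component held 51.4% of the variance, which argues against depth. Fetal sex would need libraries alike in Y-linked genes to lie together. The 5 libraries with under 100 counts over 5 Y-linked genes (AMB3, AMB5, AMB7, AMB8 and AMB10, with 23, 58, 22, 4 and 18 counts) covered 100% of the range of the component, which argues against sex as its sole source. A part of sex in it stays open: AMB4, AMB6 and AMB9, with 23732, 19805 and 15025 counts, all lay at the lower end, and the gene of largest loading (0.1096), LOC100997237 on chromosome X, had 8 to 53 counts in them and 19666 to 69138 in the others. A different share of hippocampal fields and adjoining cortex in the tissue taken was tested with lists of marker genes, leaving these out of the component. The hippocampal list (8 tested genes) had r = 0.913 (exact permutation p = 0.00012, adjusted 0.0012 over 10 relations) and rho = 0.976 (p = 0.0004, adjusted 0.004), with r = 0.657 without AMB8 and AMB10. The list of neocortical, entorhinal and subicular genes (8 tested) had r = -0.471 (exact permutation p = 0.25, adjusted 0.37) and rho = -0.238 (p = 0.58, adjusted 0.58), and r = 0.919 without AMB8 and AMB10. The most abundant members of the hippocampal list went different ways: MPPED1 was at 225 CPM in AMB8 and 577 in AMB7, PDZD2 at 42.5 and 159 CPM, and C1QL3 at 208.5 and 90.8 CPM. The cortical score was lowest in AMB8 (-0.573) and AMB10 (-0.247), highest in AMB3 (0.472) and between -0.155 and 0.159 elsewhere. RORB, already seen among the leading genes, was at 17.4 CPM in AMB8, 21.9 in AMB10 and 21.3 in AMB3. It lay between 98.4 and 268 elsewhere. FN1 was at 270 CPM in AMB8, 379 in AMB10 and 482 in AMB5. Like these genes, CUX1, FEZF2, NR4A2 and CCN2 were lowest in AMB8, whereas LAMP5 was lowest in AMB9 and SYT6 in AMB10. The explanation needs both lists, so it stays open: it may hold in part, and 8 libraries cannot decide it. The maternal groups of the design are a further open explanation, untested for want of labels.

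Over the same 10 relations, the astrocyte score had r = 0.887 with the component (exact permutation p = 0.0021, adjusted 0.011), rho = 0.857 (p = 0.011, adjusted 0.054), and r = 0.872 without AMB8 and AMB10. The interneuron score had r = -0.824 (exact permutation p = 0.0072, adjusted 0.024), rho = -0.738 (p = 0.046, adjusted 0.15), and r = -0.23 without these libraries. The first list of hippocampal markers had r = 0.849 (exact permutation p = 0.0099, adjusted 0.025), rho = 0.548 (p = 0.17, adjusted 0.34), and r = 0.391 without them, so that these 2 relations rest on AMB8 and AMB10. The other relations did not pass adjustment. Excitatory neurons had r = -0.579 (exact permutation p = 0.11, adjusted 0.23), rho = -0.619 (p = 0.11, adjusted 0.29), and r = -0.879 without AMB8 and AMB10. Meningeal genes had r = -0.419 (exact permutation p = 0.3, adjusted 0.37), rho = -0.452 (p = 0.27, adjusted 0.45), and r = 0.148 without them. Total counts had r = 0.322 (exact permutation p = 0.41, adjusted 0.46), rho = 0.286 (p = 0.5, adjusted 0.56), and r = -0.576 without them, and the mitochondrial share r = 0.263 (exact permutation p = 0.55, adjusted 0.55), rho = 0.333 (p = 0.43, adjusted 0.53), and r = 0.764 without them.

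The filter that asks for counts in every library set aside genes that were abundant in some libraries and near absent in others. A mean count of 10 admitted 2120 further genes, and 1526 of them had a log2 range of at least 2. Chosen from these after their values were seen, GPR101, an orphan receptor, had 4301 counts in AMB3 and at most 76 in any other library. OSTN, osteocrin, had between 860 and 3219 counts in AMB4, AMB5, AMB6, AMB7 and AMB9, 48 in AMB3, 2 in AMB8 and 6 in AMB10. EOMES, a transcription factor of intermediate progenitors, had 360 counts in AMB8, 189 in AMB10, 46 in AMB3 and at most 22 elsewhere. The neuropeptide NTS had 6 counts in AMB7 and between 819 and 7819 in the others.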
